A study of Mus musculus with 15 samples.

How the data were processed

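The series compared mice with a microglial deletion of Atg7 (ATG7FF with Cx3cr1CreER, called cKO here) with control mice that carried ATG7FF and no Cre. Groups were taken from the genotype labels. All mice were C57BL/6, received 1.5 mg of tamoxifen at 2 months of age and were sampled at 8 months. Single-cell libraries came from microglia gated as CD11b-high and CD45-low after a Percoll gradient, pooled from 3 control or 4 cKO forebrains, with 1 library per genotype. Bulk libraries came from single forebrain samples of mice that also carried the 5xFAD transgenes, 6 control and 7 cKO. The labels do not say in words that each bulk library is a separate mouse, so p-values measure the spread between these samples.

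The single-cell values are UMI counts per gene and barcode, made by the authors with Cell Ranger 6.1.0 per the file headers, from 10x Genomics 3' v3 libraries per the labels. The submitters' processing notes also name Seurat and the mm10 build for these libraries. The bulk values are whole-number read counts per Ensembl gene, made by the authors with HISAT2 2.0.5 and featureCounts 1.5.0-p3 on mm10 per the submitters' processing notes, from poly-A selected RNA and NEBNext Ultra II libraries per the labels. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. No normalization had been applied to either kind of deposited counts, judged from whole numbers with totals that differ between libraries. Where a gene symbol appeared on more than 1 identifier, the identifier with more counts was kept. Gene positions are from the GENCODE M21 annotation on GRCm38, the assembly also called mm10.

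Bulk counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr, scaled by TMM factors and tested with the robust quasi-likelihood F-test on genotype, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Of 54532 genes in the table, 16956 were tested. Log2 changes are cKO minus control, with standard errors (SE), and CPM were computed on TMM-scaled totals. In total 45 gene lists were fixed before the data were examined, covering microglial states, autophagy, lysosome, stress, metabolism, brain cell types and blood cells. The 42 lists with at least 5 tested members were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01, adjusted over lists. Beside it stand camera with a correlation estimated for each list, and fry, whose p tests whether a list's genes move one way on balance. Total counts ran from 16658707 to 22355512 per library, and the biological coefficient of variation was 10.0%. Chi-square values per degree of freedom between libraries of a group were all at or above 2.75, so no library repeated another within sampling noise. On data simulated for the comparison of 7 with 6 libraries over 16782 genes, the procedure called 96% of genes changed 2-fold upward, 94% of genes at 0.5-fold, 88% at 1.5-fold and 70% at 0.667-fold. Of all 197 calls, which include genes of a simulated list lowered as a group, 7 were false.

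Single-cell counts were analysed in Python 3.11.15 with scanpy 1.11.5, NumPy 2.4.6, SciPy 1.17.1 and python-igraph 0.11.9. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, 6243 of 6633 control barcodes and 8874 of 9840 cKO barcodes. Scrublet called 1 doublet in the control library and 0 in the cKO library, so doublet calling did not work and doublets remain in the data. Cells of both libraries were scaled to 10000 UMIs, log-transformed and clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, no integration). A cluster was called microglia-like when at least 3 fixed microglia markers were detected in 25% or more of its cells, and its 10 leading genes held at most 1 gene of any other cell-type list and no more markers of another class than of microglia. A cluster of cells far below the median UMI count of their own library, with no microglia marker among its 10 leading genes, stayed unnamed, which applied to 1 cluster at 0.249 of that median. UMIs of microglia-like cells were summed per library and given as CPM, with exact Poisson intervals for a sum, exact intervals for a ratio of sums and Clopper-Pearson intervals for a share, all at 95%. These intervals cover counting error only. With 1 library per genotype there is no replicate check and no p-value. A list's median log2 ratio was taken over members with at least 20 CPM in 1 library, for lists with at least 3 such members. In each alternative and within each cluster members were chosen anew by this limit, so medians of a list can rest on different genes. It was placed among 10000 random lists of the same size matched on mean expression in 20 bins. In simulated libraries the 95% intervals held the true ratio for 98% of genes at 1.5-fold, 95.9% at 2-fold, 90% at 0.667-fold and 100% at 0.5-fold, over 6635 genes. A simulated list of 34 members shifted by 1.23-fold lay at percentile 100, and 0 of 22 lists without a shift lay in the outer 5% of percentiles. The simulation drew genes independently around 1 shared profile, without variation between libraries or genes that vary together. It therefore does not show how often lists reach such percentiles in real libraries.

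The genes named in the text follow a rule fixed before the data were examined. For bulk these were Atg7, Cx3cr1, App, Sqstm1, Cdkn1a, Cdkn2a, Trem2, Apoe and Gfap, then up to 12 called genes with the largest changes each way at an average log2 CPM of at least 0, then up to 4 members of each list with the smallest p. For single cells these were Atg7, Cx3cr1, Sqstm1, Cdkn1a, Cdkn2a, Trem2 and Apoe, then the 12 highest and 12 lowest CPM ratios among genes with at least 50 CPM in the higher library, leaving out mitochondrial, Xist, Tsix and Y-linked genes, then up to 3 members of each list with the largest ratios. Some genes that the rule takes in are not reported here. Genes outside the rule are marked as chosen after their values were seen. Clec7a and Mx1 were not analysed here in the single-cell data.

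Alternatives for bulk were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, other count filters, a covariate from Xist, 1 surrogate variable (sva 3.50.0), the replicate number as a block and each library left out in turn. Xist had 0 to 2 counts in every library, so that covariate carried almost no information. For single cells they were other cell filters, Leiden resolutions, thinning of every cell to 1100 UMIs, mean CPM per cell and median-ratio scaling. A correction for GC content and exonic length, the fit without replicate 7 of the cKO group, the use of all cells that passed the filter and the ratios within each microglia-like cluster were added after the data were seen.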

Results

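Gene expression was measured after tamoxifen-induced deletion of Atg7 in microglia, to ask how loss of autophagy changes these cells and, in a model of amyloid deposition, the forebrain that holds them. Atg7 encodes the E1-like enzyme that starts the conjugation of ATG12 and LC3-type proteins during autophagosome formation. Cre recombinase came from Cx3cr1CreER, a tamoxifen-inducible knock-in at the Cx3cr1 locus, and control mice carried the floxed alleles without Cre. Single-cell RNA-seq covered sorted microglia of mice without amyloid transgenes, with 1 library pooled from 3 control forebrains and 1 pooled from 4 cKO forebrains. The control library held 9314315 UMIs over 6633 barcodes (median 1368 UMIs and 844 genes) and the cKO library 40701821 over 9840 barcodes (median 4306 UMIs and 2008 genes). Bulk RNA-seq covered forebrains of 5xFAD mice, which carry human transgenes with mutations of familial Alzheimer's disease and form amyloid plaques. The 6 control and 7 cKO bulk libraries held 16658707 to 22355512 counts each.

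The single-cell comparison asked what the deletion does to microglia outside amyloid disease. Atg7 RNA stood at 15.8 CPM in the control library and 17.5 CPM in the cKO library, a ratio of 1.10 (95% interval 0.921 to 1.33). The 3' tags count the end of the transcript, so this value does not check the deletion. The cKO library carried more RNA of the lysozyme gene Lyz2, of the cell-cycle inhibitor Cdkn1a (p21) and of the lipid carrier Apoe, and less RNA of endoplasmic reticulum (ER) chaperones and of immediate early genes. Lyz2 (chromosome 10, 117277331 to 117282321) stood at 1279 against 244 CPM, 5.25-fold higher (5.03 to 5.48). Cdkn1a (chromosome 17, 29090976 to 29100727) stood at 81.2 against 20.9 CPM, 3.89-fold higher (3.36 to 4.52), and Apoe (chromosome 7, 19696109 to 19699188) at 536 against 174 CPM, 3.08-fold higher (2.93 to 3.25). The transcription factor gene Fos (chromosome 12, 85473890 to 85477273) stood at 351 against 1624 CPM, 4.63-fold lower (4.52 to 4.74). Hspa5, which encodes the ER chaperone BiP (chromosome 2, 34771970 to 34777547), stood at 277 against 932 CPM, 3.37-fold lower (3.27 to 3.47). The other genes with the highest ratios were Tnfaip2 (3.82-fold), Pirb (2.90-fold), Blvrb (2.83-fold), the linker histone gene Hist1h1d (2.63-fold), Pde2a (2.45-fold), the glycolytic enzyme gene Eno1 (2.40-fold), Pdlim4 (2.14-fold), Txnrd1 (2.10-fold) and Gclm (2.08-fold). The other genes with the lowest ratios at this limit were Fosb (3.97-fold lower), Calr (3.90-fold), Adamts1 (3.67-fold), Sdf2l1 (3.60-fold), Egr1 (3.55-fold), Pdia6 (2.86-fold), Hsp90b1 (2.85-fold), Klf4 (2.71-fold), Fkbp2 (2.49-fold) and Manf (2.48-fold). Each genotype was 1 pooled library, so these are differences between 2 libraries with no replicate check. Among 6746 genes with at least 20 CPM, 3.17% differed by at least 1.5-fold, and the median log2 ratio was 0.04.

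**Figure D1:**
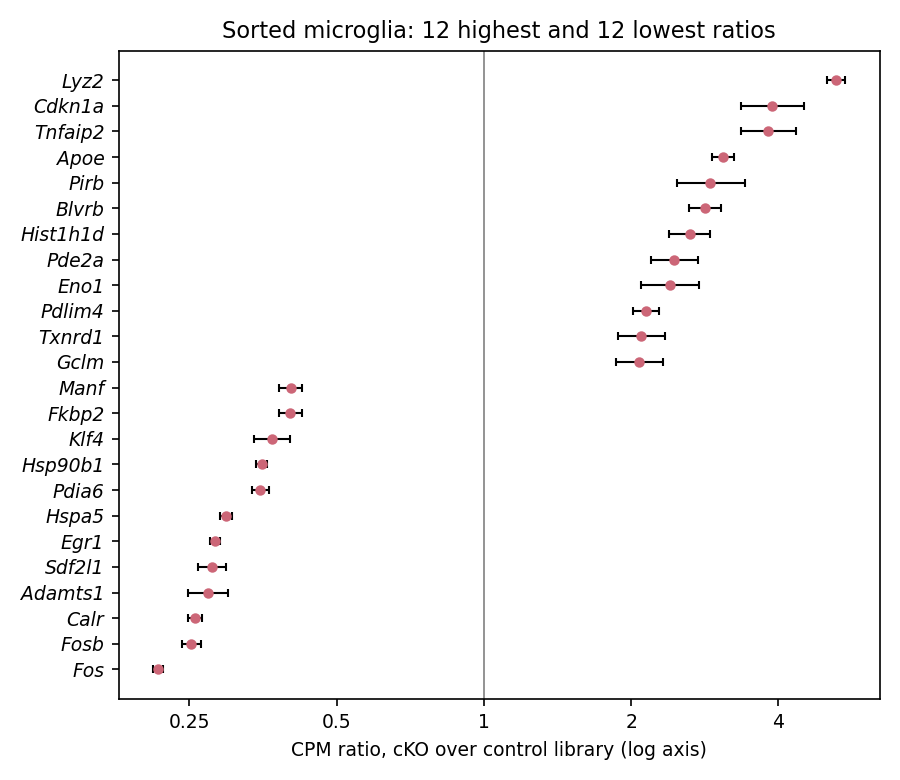
Ratio of CPM in the cKO library over the control library (log axis) for the 12 genes with the highest and the 12 with the lowest ratios in microglia-like cells. Only genes with at least 50 CPM in the higher library were ranked. Points are ratios of summed UMIs and bars are 95% exact intervals for counting error, and the points run from 0.216 for Fos to 5.25 for Lyz2.

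Genes that respond to oxidative stress and to p53 were higher as groups in the cKO library. All 17 measured NRF2 targets, which serve antioxidant defence and detoxification, had higher CPM, 8 of them by at least 1.5-fold. They included Gstm1 (4.84-fold, 3.49 to 6.89), Blvrb (84.7 to 240 CPM) and the glutathione reductase gene Gsr (2.29-fold, 1.91 to 2.77). The list's median log2 ratio was 0.51, at percentile 100 among matched random lists. In the list of cell-cycle arrest and p53 targets 8 of 11 members were higher, with a median of 0.35 (percentile 100). Beside Cdkn1a these included Trp53inp1 (2.03-fold, 1.67 to 2.49) and Ccng1 (1.64-fold, 1.39 to 1.95). Cdkn2a, which encodes the senescence marker p16, had 10 UMIs in the control and 84 in the cKO library, a ratio of 1.99 (1.03 to 4.29). Disease-associated microglia genes, a set known from microglia around plaques, had a median of 0.30 (percentile 100), with 14 of 16 higher. Among them Lpl, a lipoprotein lipase, stood at 30.7 against 5.28 CPM (5.81-fold, 4.36 to 7.93) and Cst7, a cathepsin inhibitor, at 22.4 against 6.82 CPM (3.29-fold, 2.54 to 4.33), while Trem2, a lipid-sensing receptor, had a ratio of 1.01. The lipid handling list had a median of 0.35 (percentile 99.98), with 7 of 8 higher, led by Lpl, Apoe and the lysosomal lipase gene Lipa (1.86-fold, 1.74 to 1.99).

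Genes of the ER stress list, mostly chaperones, were lower in the cKO library. Its median log2 ratio was -1.21 (percentile 0), with 10 of 14 members lower by at least 1.5-fold, among them Calr (719 to 184 CPM). Genes of dissociation and the immediate early response had a median of -0.70 (percentile 0), with 9 of 16 lower by at least 1.5-fold. The neuronal activity list, whose 5 measured members Fos, Fosb, Egr1, Junb and Dusp6 are early response genes also used by microglia, had a median of -1.83 (percentile 0). The NF-kB and cytokine list had a median of -0.14 (percentile 0.03), with the chemokine gene Ccl3 1.82-fold lower, Nfkbiz 1.73-fold lower and Il6 1.63-fold lower. Within cluster 3, microglia-like cells led by Lyz2 and lysosomal genes, the median was 0.052 over members chosen anew. Ccl3 and Nfkbiz were lower in that cluster too, with ratios of 0.296 and 0.382. Senescence-associated secretion genes had a median of -0.03 (percentile 14.23), with Ccl4 1.60-fold lower. Without clusters under 5% of a library the median was 0.024.

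Median log2 ratios of the autophagy machinery and of lysosomal, homeostatic and plaque-induced genes lay near 0, while autophagy receptors and Cx3cr1 differed more. The autophagy machinery had a median of 0.07 (percentile 68.15), with Gabarapl1 1.68-fold higher and Ulk1 1.47-fold higher. Its median was -0.0022 within cluster 1 and -0.060 within cluster 3. Autophagy receptors had a median of 0.21 (percentile 98.96), with 8 of 9 higher and Sqstm1, which encodes p62, at 153 against 101 CPM (1.52-fold, 1.42 to 1.64). Lysosomal genes had a median of -0.02 and a mean of 0.02 (percentile 12.13). Homeostatic microglia genes had a median of -0.06 (percentile 8.22), but 0.042 within cluster 0. The lowest ratio among these was that of Cx3cr1 (chromosome 9, 119901616 to 120069879), the gene that carries the CreER insertion in cKO mice, at 2816 against 5347 CPM (1.90-fold lower, 1.88 to 1.92). Selplg was 1.28-fold lower and Cst3 1.25-fold lower. Plaque-induced genes had a median of 0.01 (percentile 40.17), which lay below 0 in 5 alternatives, down to -0.043 with median-ratio scaling.

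Microglia-like cells made up 99.7% of the control cells (99.6 to 99.9) and 86.6% of the cKO cells (85.9 to 87.3), which leaves 6226 and 7686 cells with medians of 1392 and 4796 UMIs. The gap was set by a cluster of low-UMI cells, left unnamed by the UMI rule, with 12.9% of the cKO and 0.0801% of the control cells, and all cells came from a CD11b-high, CD45-low gate. In that cluster 18 fixed microglia markers were detected, as in the microglia-like clusters. Its cKO cells had a median of 1126 UMIs, against 1387 for the control cells kept in cluster 0. The rule compares cells with the median of their own library, so the gap does not show fewer microglia in the cKO sort. Different clusters held most microglia-like cells of each library. Cluster 0 held 89.6% of the control and 4.94% of the cKO cells, cluster 1 held 5.69% and 52.0%, and cluster 3 held 4.50% and 29.6%. Early response and chaperone genes lead cluster 0, histone genes and Apoe lead cluster 1, and Lyz2 and lysosomal genes lead cluster 3. Since these genes differ between the libraries, cluster sizes are not a separate difference. Within clusters 0, 1 and 3 the cKO over control ratio was 3.71, 1.65 and 2.29 for Cdkn1a, 2.25, 2.45 and 4.96 for Lyz2, 1.37, 1.18 and 3.11 for Apoe, 0.565, 0.379 and 0.309 for Fos, and 0.426, 0.339 and 0.278 for Hspa5. The median of the arrest list was 0.16, 0.21 and 0.49 in these clusters, and 0.16 over cells with at least 1000 genes. The median of the disease-associated list was 0.19, 0.24 and 0.33, that of lipid handling 0.17, 0.047 and 0.18, and that of autophagy receptors 0.047, 0.090 and 0.32. Medians of the lower lists were -0.23, -0.40 and -0.78 for dissociation and immediate early genes, and -0.42, -1.14 and -1.59 for neuronal activity genes. The NF-kB median was -0.25 and the secretion median -0.26 within cluster 1.

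The bulk comparison asked what the same deletion does to the forebrain of 5xFAD mice. Atg7 (chromosome 6, 114643097 to 114860614) stood at 24.3 ± 2.09 CPM in the controls (SD, n = 6) and 24.3 ± 1.32 CPM in the cKO mice (SD, n = 7), with a log2 change of 0.01. All forebrain cell types contribute to these counts, which do not separate exons, so they do not check the deletion. Microglial genes fell in the cKO forebrains, among them Itgax, Cst7 and Clec7a of the disease-associated list. Itgax, which encodes the integrin CD11c (chromosome 7, 128129547 to 128150657), stood at 8.08 ± 2.37 CPM in controls and 1.85 ± 0.248 CPM in cKO mice (log2 change -2.11, SE 0.16, adjusted p = 6.79e-08). Cst7 (chromosome 2, 150570415 to 150578944) stood at 14.6 ± 4.38 and 3.39 ± 0.862 CPM (log2 change -2.10, SE 0.18, adjusted p = 3.70e-06). Clec7a, the beta-glucan receptor Dectin-1 (chromosome 6, 129461591 to 129472779), stood at 8.20 ± 2.90 and 2.96 ± 0.520 CPM (log2 change -1.47, SE 0.18, adjusted p = 0.000137). Cx3cr1, the gene that carries the CreER insertion in cKO mice only, stood at 63.1 ± 2.99 and 24.4 ± 2.99 CPM (log2 change -1.37, SE 0.07, adjusted p = 5.03e-11). Trem2 (chromosome 17, 48346401 to 48354147) stood at 28.5 ± 4.18 and 14.6 ± 1.36 CPM (log2 change -0.96, SE 0.09, adjusted p = 7.74e-07). For these 5 genes all 7 cKO libraries lay below all 6 controls.

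**Figure D2:**
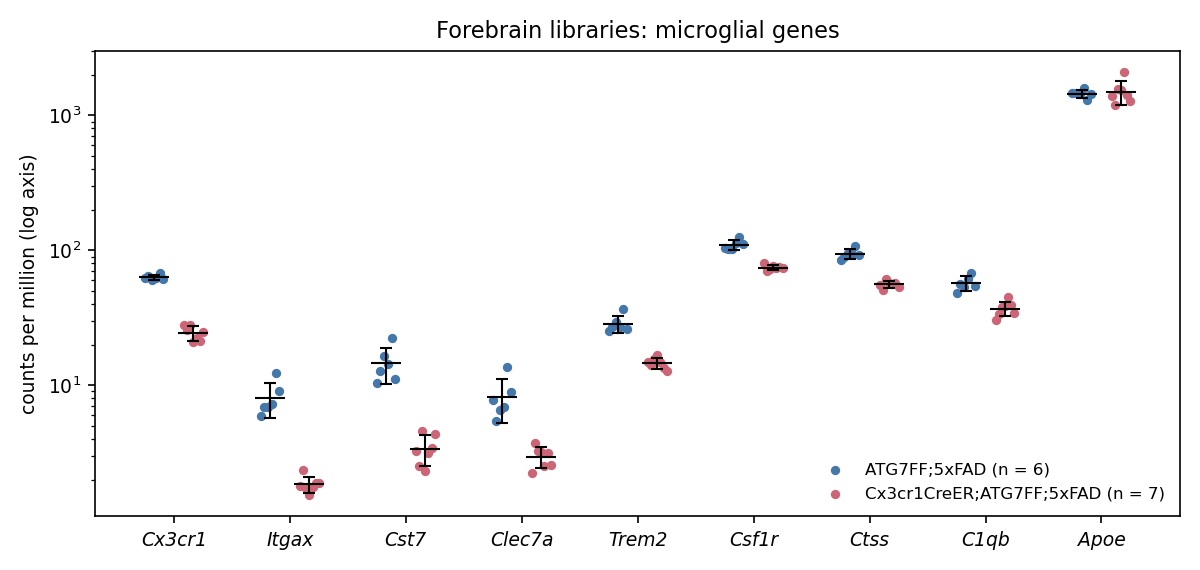
CPM (log axis) of 9 genes in each 5xFAD forebrain library, controls in blue (n = 6) and cKO in red (n = 7), with the mean and SD as bars. The cKO libraries lie below all controls for Itgax, Cst7, Clec7a, Cx3cr1, Trem2, Csf1r, Ctss and C1qb, while Apoe overlaps.

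By edgeR's quasi-likelihood test 47 genes fell and 9 rose at an adjusted p threshold of 0.05, and 27 of the 47 fell by at least 1.5-fold. In 40 of the 47 all cKO libraries lay below all controls. Of the 16956 genes tested, 53 were fully separated downward and 22 upward, where chance gives 0.0583% of these genes on average in each direction. Genes vary together, so such counts can stray from that share, and the 22 were not tested against chance. Other large falls were those of Ccl6 (log2 change -1.49, adjusted p = 0.0261), Fcrls (-0.82, 3.75e-05), Crybb1 (-0.81, 0.0261), the inhibitory Fc receptor gene Fcgr2b (-0.78, 0.00339), Rasal3 (-0.78, 0.0338) and Ly86 (-0.77, 0.00414). With 1 library left out, 3 of these lost their call. Ccl6 did so without control 2, 3 or 6 or cKO 4, 5 or 6 (adjusted p = 0.0564 to 0.125), Crybb1 without control 1, 2, 3, 5 or 6 or cKO 2, 4, 6 or 7 (0.0542 to 0.0707) and Rasal3 without control 2, 3, 5 or 6 or cKO 2, 3, 4 or 6 (0.0765 to 0.116). The count of genes that fell was 30 without control 5, 31 without cKO 3 and 31 without cKO 6, and at least 33 in the other 10 such fits. Across genes, the log2 change correlated with GC content (Spearman 0.37) and with exonic length (-0.21), and after a correction for both 44 of the 47 genes were still called.

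Grouped by the fixed lists, 8 of 22 homeostatic microglia genes fell (14 when adjusted over the list alone), with a median log2 change of -0.35 (camera adjusted p = 2.84e-27, and adjusted p = 0.000474 with an estimated correlation). Among these was the growth factor receptor gene Csf1r (110 ± 9.02 to 74.6 ± 3.30 CPM, log2 change -0.56). Of 26 disease-associated microglia genes 7 fell (11 fell and 1 rose when adjusted over the list alone), with camera adjusted p = 2.73e-17 (adjusted p = 0.00878 with an estimated correlation). Its median log2 change was -0.14, and the lipid carrier Apoe did not pass the test (1453 ± 98.8 and 1499 ± 299 CPM, log2 change 0.04). Of 51 plaque-induced genes, which include Cx3cr1, Trem2 and Csf1r, 19 fell (29 fell and 2 rose when adjusted over the list alone; camera adjusted p = 3.74e-40, and adjusted p = 0.00878 with an estimated correlation). Of 35 lysosomal genes 6 fell (13 when adjusted over the list alone; camera adjusted p = 5.30e-14, and adjusted p = 0.0116 with an estimated correlation), among them the cathepsin gene Ctss (chromosome 3, 95526786 to 95556403; log2 change -0.74, adjusted p = 5.91e-08), the mannosidase gene Man2b1 (-0.32, 0.00414) and Grn, which encodes progranulin (-0.30, 0.00414). These 4 lists share members and are the lists whose call held with an estimated correlation. By the fry test for change in one direction the same 4 lists and the complement list were called.

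Of 12 complement genes 4 fell (5 fell and 1 rose when adjusted over the list alone; camera adjusted p = 2.47e-05, and adjusted p = 0.0665 with an estimated correlation). They were C1qa (log2 change -0.68, adjusted p = 0.0178), C1qb (-0.62, 0.000409), C1qc (-0.66, 0.00124) and Itgam, which encodes CD11b (-0.76, 0.00153). C1qa lost its call without control 4, control 5 or cKO 3 (adjusted p = 0.0512, 0.0692 and 0.0558). Of 5 dendritic cell markers only Siglech, which microglia also express, fell (log2 change -0.63, adjusted p = 0.000681), and that list was not called (adjusted p = 0.212).

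The 9 genes that rose included Clec3b, which encodes tetranectin (chromosome 9, 123150946 to 123157432; 1.87 ± 0.622 to 4.18 ± 1.01 CPM, log2 change 1.13, adjusted p = 0.00543), and Mmp12, a macrophage metalloproteinase (chromosome 9, 7344381 to 7369499; 0.193 ± 0.188 to 1.45 ± 0.736 CPM, log2 change 2.83, SE 0.48, adjusted p = 0.00583). In both genes all 7 cKO libraries lay above all 6 controls, and both were called in all 13 fits with 1 library left out. Dennd6b (log2 change 0.29, adjusted p = 0.0150) was also called in all 13. Wwox (0.36, 0.0281), Abcc10 (0.34, 0.0496), Leng8 (0.29, 0.0261) and Coro6 (0.27, 0.0496) rose as well. Lilr4b (1.70, 0.0174) and B430306N03Rik (1.70, 0.0496), named after their values were seen, rose from means of 0.231 and 0.271 CPM, and reads of Lilr4b are uncertain since it belongs to a family of close paralogs. Wwox lost its call without control 3, 4, 5 or 6 or cKO 1, 2, 3 or 7 (adjusted p = 0.0523 to 0.0967), Abcc10 without any control or cKO 2, 3, 4, 5, 6 or 7 (0.0629 to 0.137), Leng8 without any control or cKO 6 or 7 (0.0527 to 0.0769), Coro6 without any control or cKO 2, 3, 4, 6 or 7 (0.0606 to 0.146), Lilr4b without control 2, 3 or 4 (0.0510 to 0.0619) and B430306N03Rik without control 1, 2, 3, 4 or 5 (0.0689 to 0.157). Lilr4b and B430306N03Rik were each left out by the count filter, and so not tested, in 6 of the 7 fits without a cKO library. The count of genes that rose was 23 without cKO 1, 3 without control 3, control 4 or cKO 7, 4 without control 2 or cKO 2, and 5 without control 5, control 6 or cKO 6.

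App, the autophagy receptor gene Sqstm1, Cdkn1a and the astrocyte gene Gfap did not pass the test in forebrain. The log2 change was -0.02 for App (1828 ± 27.2 and 1804 ± 28.7 CPM), 0.04 for Sqstm1, -0.03 for Cdkn1a and -0.07 for Gfap, with adjusted p from 0.795 for Gfap to 0.969 for Cdkn1a. Human transgene reads were not analysed here. Cdkn2a had 0 to 6 counts per library, too few to test. The lists of cell-cycle arrest and p53 targets (camera adjusted p = 0.809), senescence-associated secretion (0.325, with Mmp12 its 1 called member), autophagy machinery (0.809), autophagy receptors (0.205), NRF2 targets (0.669), ER stress (0.559), lipid handling (0.696), reactive astrocyte genes (0.576) and NF-kB and cytokine response (0.212) were not called. Other forebrain cells also contribute to the counts of these genes and lists, so a change in microglia alone could be missed. By fry's test for change in either direction the secretion list (adjusted p = 2.75e-05) and the NF-kB list (adjusted p = 2.47e-07) were called. Adjusted over the list alone, 2 secretion genes fell and 1 rose, and 3 NF-kB genes fell. In the NF-kB list Ccl3 had a log2 change of -1.18 (adjusted p = 0.0836, and 0.00466 without cKO 5).

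**Figure D3:**
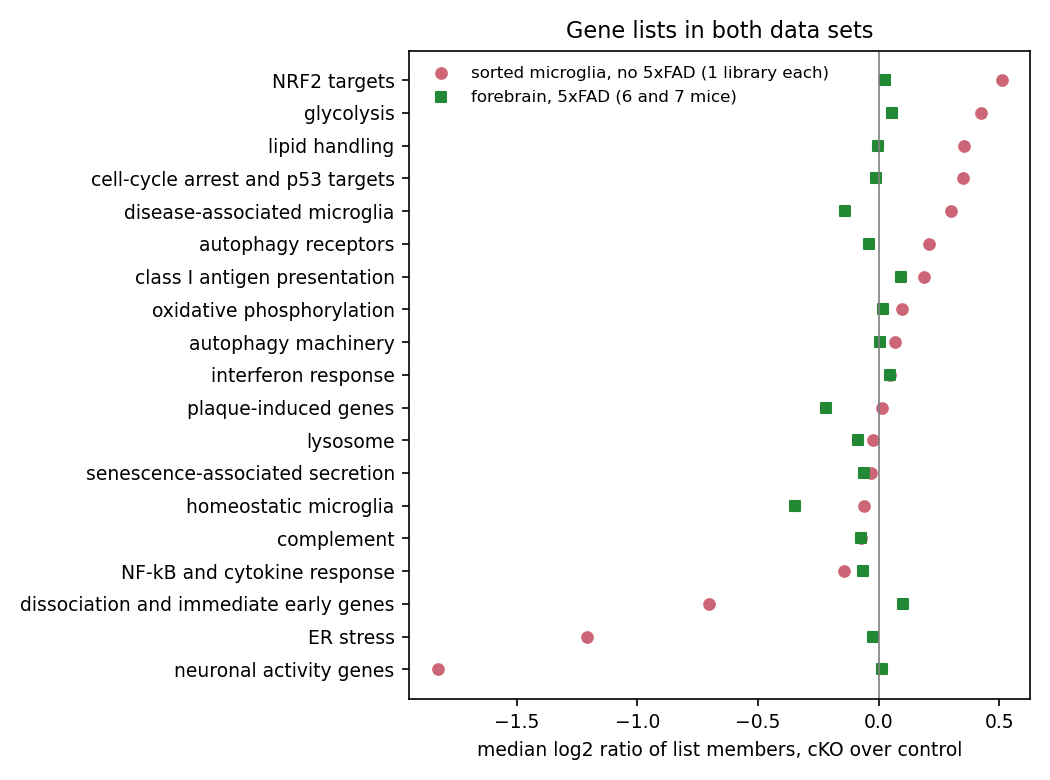
Median log2 ratio of list members, cKO over control, for 19 gene lists in sorted microglia without 5xFAD (circles, 1 library per genotype) and in 5xFAD forebrain (squares, 6 and 7 libraries). NRF2 targets lie at 0.51 in sorted microglia and 0.03 in forebrain, ER stress genes at -1.21 and -0.03, and homeostatic microglia genes at -0.06 and -0.35. Circles use members with at least 20 CPM in 1 library and squares all tested members. For NRF2 targets these are 17 and 25 genes, and for ER stress 14 and 17.

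A comparison of the changes in both data sets asked whether microglial genes moved the same way with and without 5xFAD. Over 67 genes of the microglial lists the Spearman correlation across genes was 0.41 and the Pearson correlation 0.12, and over all 6548 genes with at least 20 CPM in microglia-like cells the Spearman correlation was 0.0487. Over the 47 of these genes that were called in forebrain it was 0.066, with 28 lower in both data sets, 2 higher in both and 17 lower in cKO forebrain and higher in the sorted cKO microglia. Genes are not independent replicates, so no p-value was computed. Of the 67 genes 33 were lower in both data sets, 7 were higher in both, and 27 were lower in cKO forebrain and higher in the sorted cKO microglia. Cst7 had a log2 change of -2.10 in forebrain and 1.72 in sorted microglia, Apoe 0.04 and 1.62, Trem2 -0.96 and 0.01, and Cx3cr1 -1.37 and -0.93. Lyz2, named here after its values were seen, had 0.32 and 2.39, with a forebrain adjusted p of 0.503 that became 0.0129 without control 5. The data sets differ in amyloid, in tissue and in assay, and the difference between them was not tested.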

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

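The tests of the explanations weighed here were all chosen after the results had been seen, though thinning itself had been planned as an alternative.

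In 5xFAD forebrain, microglial genes were lower in the cKO mice, with a mean log2 change of -0.58 over the 17 fixed markers other than Cx3cr1, from -0.96 for Trem2 to -0.05 for Sall1. GC content and gene length are argued against as the whole cause, since the median log2 change of the homeostatic list was -0.39 after a correction for both and -0.35 before. The 24 tested genes of the disease-associated list outside the markers had a mean of -0.38, a difference of 0.20 from the markers (SD 0.044 over 6 controls and 0.064 over 7 cKO, exact two-sided permutation p = 0.000583, the smallest that its splits can give). An even loss of microglia may account for part of the pattern and stays open. Other brain cells also express members of that list, which would make its fall smaller. Such expression would not make a fall larger, and Itgax (-2.11), Cst7 (-2.10), Ccl6 (-1.49) and Clec7a (-1.47) fell further than any marker. These were picked as the largest falls, and the other members outside the markers fell less than Trem2 or rose. Lower expression in microglia without Atg7 may account for the pattern as well. The CreER knock-in at Cx3cr1 cannot be told apart from either, because 0 control libraries carry CreER.

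In sorted microglia without 5xFAD, ER chaperone genes such as Hspa5 and Calr and early response genes such as Fos and Egr1 were lower in the cKO library. The median log2 ratio of the ER stress list was -1.24 after every cell was thinned to the same depth and -1.21 before. Random thinning hardly moves a ratio of CPM, so these values do not decide on sequencing depth. Handling or the run of the 2 libraries may account for the pattern, since early response genes are known to react to tissue dissociation. With 1 library per genotype, handling cannot be told apart from an effect of Atg7 loss or of the CreER knock-in, which the control library lacks.

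Lyz2, Apoe, Cdkn1a and NRF2 targets were higher in the cKO library of sorted microglia. The NRF2 list had a median log2 ratio of 0.42 after thinning, which does not decide on sequencing depth, since random thinning hardly moves such a ratio. For Lyz2, border macrophages in the cKO sort are argued against. Their markers Mrc1 and Pf4 together were 8.03 CPM higher (Mrc1 4.73 to 12.9 CPM, Pf4 0.660 to 0.520 CPM), where Lyz2 was 1035 CPM higher. The CD45-low gate is also set to leave such cells out. The comparison was set for Lyz2 alone and does not decide on Apoe (362 CPM higher), Cdkn1a or the NRF2 targets. A response to lost autophagy in microglia may account for the pattern. Handling or run stays open, with 1 library per genotype, and so does the CreER knock-in, which the control library lacks.

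In forebrain, 9 times a library stood far from the rest of its group in the CPM of a gene, among 106 groups examined, where chance gives 5.3 (about 1 in 20). Control 5 had Trem2 at 36.6 CPM (other controls 25.2 to 29.4) and Lyz2 at 33.4 CPM (19.6 to 22.7). Control 4 had P2ry12 at 31.9 CPM (39.0 to 42.1) and Isg15 at 2.62 CPM (0.973 to 1.40). In the cKO group, replicate 5 had Sqstm1 at 541 CPM (431 to 478), Apoe at 2101 CPM (1186 to 1575) and C1qc at 39.8 CPM (24.6 to 30.3). Lyz2 in cKO 3 was 21.7 CPM (28.3 to 31.7), and Mobp in cKO 4 was 648 CPM (527 to 575).

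Cst7 had a log2 ratio of 1.72 in sorted microglia and a log2 change of -2.10 in 5xFAD forebrain, and the difference was not tested. An unnamed cluster of low-UMI cells, left out of the comparisons, held 12.9% of the cKO cells and 0.0801% of the control cells, at a median of 1126 UMIs. It had 18 fixed microglia markers detected and was left out for its UMI count alone. Another unnamed cluster, led by Ttr and Enpp2, held 0.496% of the cKO and 0.176% of the control cells.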

How the results depend on the processing

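The correction for GC content and length, the fit without replicate 7 of the cKO group, the use of all cells that passed the filter and the ratios within single clusters were tests chosen after the data were seen. Of the alternatives for forebrain genes named or taken in by the naming rule 634 kept their side of the threshold, 54 lost the call and 4 gained one, and for forebrain lists 490 kept their side, 11 lost the call and 3 gained one. The sign changed in 10 alternatives over 5 of these genes and in 34 over 11 of these lists, none of them called, with values up to 0.050 and 0.084 from 0. Of the single-cell list medians 168 stayed within the counting interval of the main median and 75 moved beyond it. Another 10 changed sign from a median whose counting interval excludes 0. With those near 0 counted, 26 changed sign. Of the single-cell gene ratios 380 stayed within the counting interval of the main ratio and 191 moved. These labels leave out the counting error of the alternative itself, which is larger within a cluster. Gsr in cluster 1 counts as moved at 5.16-fold (2.01 to 19.0, with 4 control UMIs), an interval that holds its main ratio. The cause of the changes was not tested. Depth limits the control microglia more than the cKO microglia, at medians of 1392 and 4796 UMIs per cell.

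The count of higher forebrain genes, 9, became 16 with DESeq2 (6 of them shared), 5 with limma-voom and 23 without a count filter (8 shared), and ran from 3 to 23 with 1 library left out. The count of lower genes, 47, ran from 30 to 50 with 1 library left out, and DESeq2 called 62, with all 47 among them. Cd68 lost its call without control 1, 2, 3 or 5 or cKO 2, 3, 4 or 7 (adjusted p = 0.0589 to 0.107 by edgeR), and Tmem119 gained one without cKO 1 (0.0493). Called lists went from 10 to 4 with an estimated correlation.

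Replicate numbers are shared between the groups, but nothing in the labels says that they pair mice. Same-numbered libraries had correlations of 0.21, 0.03, -0.13, 0.31, -0.52 and 0.23 in their deviations from the group means, and 0 of them correlated best with its own number. With the replicate number as a block 1 gene was higher and 19 were lower, against 3 and 34 without the block over the same 12 libraries.

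The microglia-like share of the cKO cells was 85.6% at Leiden resolution 1.0, 81.4% with at least 200 genes and at most 5% mitochondrial UMIs, 99.04% with at least 1000 genes and 85.9% with doublets kept. Keeping doublets added back only the 1 called control cell, so that setting says little about doublets. The control share was 98.4% and 99.2% under the same 200 and 1000 gene minimums. The median log2 ratio of the arrest list was 0.16 with at least 1000 genes, and 0.16, 0.21 and 0.49 within clusters 0, 1 and 3. That of disease-associated genes was 0.26 with the mean CPM per cell, 0.24 with median-ratio scaling, 0.26 without clusters under 5% of a library, and 0.19, 0.24 and 0.33 within clusters 0, 1 and 3. Within cluster 0 the NRF2 median was 0.34 and the ER stress median -0.91. The proliferation median was 0.37 over 3 genes. Over members chosen anew at 20 CPM it was -0.20 with at least 1000 genes, -0.68 within cluster 1 and -0.71 within cluster 3. Within clusters 1 and 3 the ratio was 0.996 and 0.991 for Stmn1 and 1.15 and 2.05 for Mcm3. Other members therefore set these cluster medians, which do not show a reversal of the same genes. Other medians whose counting interval excludes 0 and that changed sign within a cluster were those of the homeostatic list (0.042 in cluster 0), complement (0.033 in cluster 0, 0.011 in cluster 1), class II (0.021 in cluster 1), autophagy machinery (-0.0022 in cluster 1, -0.060 in cluster 3) and NF-kB (0.052 in cluster 3). After thinning to 1100 UMIs per cell (1086 control and 186 cKO cells were shallower and left out) and clustering again, 63.9% of one library's cells would have to change cluster to match the other, 66.3% at resolution 0.3, 65.2% at 1.0 and 78.8% without thinning. The genes that lead these clusters differ between the libraries, so the value is no separate difference. The correlation of forebrain and microglia changes was 0.41 over microglial lists, 0.0487 over all genes and 0.066 over genes called in forebrain.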

Other observations

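Of the tests on other splits of the forebrain libraries, those of gene counts and of lists with the preset correlation were chosen after the results had been seen, as were the ratios within clusters, and the one of lists with an estimated correlation before.

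In sorted microglia without 5xFAD, genes of energy metabolism and class I antigen presentation had higher ratios in the cKO library. Of 14 glycolysis genes 11 were higher, with a median log2 ratio of 0.42 (percentile 100), led by Eno1 and by Pkm (1.78-fold, 1.67 to 1.90). Of 27 oxidative phosphorylation genes 22 were higher by small amounts, with a median of 0.10 (percentile 98.39), which ran from 0.037 over all cells that passed the filter to 0.27 within cluster 1. Of 11 class I genes 9 were higher, with a median of 0.19 (percentile 99.12), led by B2m, the invariant light chain (1.37-fold, 1.34 to 1.40). Class II genes had a median of -0.25 over 3 members (percentile 1.175), but -1.37 over cells with at least 1000 genes and 0.021 within cluster 1. Complement genes had -0.07 with a mean of 0.01 (percentile 14.69), but 0.033 within cluster 0 and 0.011 within cluster 1. Interferon response genes had 0.05 (percentile 44.65), and -0.16, -0.49 and -0.48 within clusters 0, 1 and 3. The proliferation list had 3 measured members, with Stmn1 1.49-fold and Mcm3 1.29-fold higher and Pcna 1.16-fold lower (median 0.37, percentile 99.485, but -0.20 over cells with at least 1000 genes). Medians within clusters and over cells with at least 1000 genes rest on members chosen anew at 20 CPM, so they can cover different genes. The disease-associated oligodendrocyte list had a median of 0.41 (percentile 99.98, and 0.17 within cluster 0), but its 4 measured members (Sgk1, H2-D1, Cd63 and B2m) are genes that microglia express, and oligodendrocyte markers had 0.01 (percentile 31.32), which ran from -0.052 with median-ratio scaling to 0.20 within cluster 3. The other lists had fewer than 3 members at 20 CPM.

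In 5xFAD forebrain, camera with the preset correlation also called lists of other cell types, and each of these calls was lost with an estimated correlation. Oligodendrocyte markers (median log2 change -0.08, adjusted p = 0.00039, and adjusted p = 0.188 with an estimated correlation) were lower as a list, with 0 of 16 called over all genes and 2, Mobp among them, when adjusted over the list alone. Mobp was called without cKO 4 (adjusted p = 0.0452). Synapse genes (median -0.04, adjusted p = 0.00214, and adjusted p = 0.438 with an estimated correlation) and neutrophil markers (median -0.47 over 5 genes, adjusted p = 0.000593, and adjusted p = 0.188 with an estimated correlation) were lower as lists. Only 5 of the 12 neutrophil markers were tested. In the sorted microglia-like cells 1 member of that list reached 20 CPM, so it does not measure neutrophils alone. Olfactory bulb markers were higher as a list (median 0.14, adjusted p = 0.0079, and adjusted p = 0.351 with an estimated correlation), a call lost without control 5 (0.0520) or cKO 1 (0.0518). Glycolysis genes were called higher (median 0.06, mean -0.09, adjusted p = 0.0470, and adjusted p = 0.656 with an estimated correlation), where the mean is set by Gapdh, which ran from 4.92 to 152 CPM among controls. Whether Gapdh shares reads with pseudogenes was not tested. The call of the glycolysis list was lost without control 1 (0.0699), control 2 (0.0544), control 4 (0.0655), control 5 (0.0860), cKO 3 (0.0663), cKO 4 (0.0964) or cKO 5 (0.252).

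Border macrophage markers were not called as a list in forebrain (adjusted p = 0.669, median -0.01 and mean 0.04), while fry's test for change in either direction gave an adjusted p of 5.30e-05. When adjusted over the list alone 2 members were higher, Stab1 (log2 change 0.34) and Ms4a7 (1.14). Over all genes Stab1 had adjusted p = 0.105 by edgeR (0.0371 without cKO 3) and Ms4a7 0.283.

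The remaining forebrain lists were not called, with camera adjusted p of 0.366 for interferon response, 0.112 for class I, 0.301 for class II, 0.705 for proliferation, 0.366 for cholesterol synthesis, 0.559 for oxidative phosphorylation, 0.212 for immediate early genes, 0.974 for neuronal activity, 0.325 for excitatory neurons, 0.444 for inhibitory neurons, 0.809 for striatal neurons and 0.669 for thalamus and hypothalamus. Glial and vascular lists gave 0.212 for homeostatic astrocytes, 0.366 for disease-associated oligodendrocytes, 0.112 for oligodendrocyte precursors, 0.809 for endothelium, 0.870 for pericytes, 0.364 for fibroblasts, 0.212 for ependyma, 0.270 for choroid plexus and 0.809 for T and NK cells. With 1 library left out, class I genes were called without control 2 (0.0386) or cKO 7 (0.0378), precursors without control 1 (0.0476) or cKO 1 (0.0222), and immediate early (0.00456) and neuronal activity genes (0.0172) without cKO 1. Red blood cell, monocyte and B cell lists had fewer than 5 tested members.

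Among 100 splits of the 13 forebrain libraries into 6 and 7, the real one included, chance can be excluded for the 47 lower genes (1 split with as many, highest other 1). For the 9 higher genes 1 split gave as many (highest other 1). The p-values were adjusted over both directions together, so the lower genes of the real split made calls of higher genes easier. These splits therefore do not decide on chance for the higher genes. Chance can be excluded for the 4 lists called with an estimated correlation (1 split, highest other 2), but not for the 10 lists called with the preset correlation, since 24 splits gave as many, up to 16.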
